A study of Mus musculus with 2 samples.

How the data were processed

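RNA sequencing of mouse pancreas progenitor spheres was compared between a scrambled hairpin control (shScramble, 1 sample) and a hairpin against Wdr5 (shWdr5, 1 sample). Samples were placed in groups from their titles. Libraries were made with Illumina TruSeq kits, of which the protocols name both an RNA sample preparation kit and a stranded mRNA kit, and were read on HiSeq or NextSeq instruments, without saying which sample had which. Spheres treated with a hairpin against Dpy30, named in the protocols, were not analysed here.

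Reads were assigned with Salmon to the mouse mm10 genome and compared with DESeq2 by the authors, per the labels' protocols. Versions, filters, shrinkage, strand settings and the number of libraries in each group were not given in the sources used here. The deposited values analysed were 1 table of that comparison, with no value per library, so neither depth per sample nor counting intervals could be given and no count model was run. The mean normalised count, a signal averaged by the authors over all libraries after scaling, is not a count of reads, and its name is read per the file headers. The deposited log2 fold change and its standard error are those of the authors' comparison. The deposited Wald score equalled the log2 fold change divided by its standard error, to within 4.11e-08. The deposited p-value is from the DESeq2 Wald test run by the authors, and the Benjamini-Hochberg adjusted p-value was recomputed from it to within 5.48e-05. It was left empty for 1432 genes, all with a mean of 6.34 or less, which stayed out of all counts of calls. The sign is not explained in the table. Since Wdr5 has a negative value, fold changes were read as shWdr5 over shScramble, and every direction rests on that reading. P-values from an unstated number of libraries, each described as a pool of more than 4 differentiations, measure the spread between those libraries only.

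The plan made before the data were examined foresaw values per library and, where these were lacking, use of the authors' fold changes with their mean of at least 30 as the expression minimum. It set the count of genes at least 2-fold higher or lower, and for each of 26 gene lists the number of members over the minimum, their median and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A percentile of 0 means that no random list had a median as low. It describes these data and is not a p-value, since genes are not independent replicates. Lists with under 5 members over the minimum would have had no percentile. Counts of genes past an adjusted p of 0.05, over all genes or adjusted over the list alone, were added once the table was seen to hold the authors' p-values. Genes are described as rising or falling only where the authors' adjusted p was under 0.05.

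Genes were named by a rule fixed in advance. It took Wdr5 and the other TrxG and COMPASS subunits, the 12 genes with the highest and the 12 with the lowest fold change past an adjusted p of 0.05 with a mean of at least 30, and up to 4 members of each list with the largest absolute fold change. Pdx1, Ptf1a, Sox9, Neurog3, Cpa1, Ins1, Ins2, Gcg, Krt19, Cdkn1a, Mdm2, Trp53 and Mki67 were named whatever their change. Gene models without an assigned name, 95 among the called genes, were left out of the ranking. A few genes that the rule takes are not reported here. Other genes are said to have been picked out after their values were seen. The lists covered TrxG and COMPASS subunits, NSL complex and other WDR5 partners, pancreas progenitor factors, acinar, endocrine progenitor, islet hormone and secretory, and ductal genes, p53 targets, cell cycle, Notch, Wnt, retinoic acid, unfolded protein and amino acid stress, interferon, hypoxia and glycolysis, cholesterol synthesis, ribosomal protein, histone, Hox and mitochondrially encoded genes. Markers of mesenchyme, endothelium, immune cells, neural crest and neurons, and erythroid cells and genes of stomach, gut and liver stood for other cells the buds could hold. A few genes, among them Hes1 and Dll1, stood in more than 1 list. A further 5 lists, on receptor families of other organs, YAP and TAZ targets, NRF2 targets, stomach gland and forestomach genes, and structured RNA, were written after the table was seen. Their main results stand in the closing section except those on structured RNA, of which the 3 members over the minimum, Lars2, Rpph1 and Rmrp, are given with the stomach genes.

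Entrez gene identifiers matched a RefSeq gene table of assembly GRCm38.p6, the same build as mm10, for 18441 genes (99.9%), of which 16598 were protein coding. Coordinates are from that table and count from 1. Intervals reach 1.96 deposited standard errors to each side. The steps were tested on simulated data in which 200 of 14716 genes carried a known change under the deposited standard errors. Of 2-fold, 4-fold and 8-fold changes, 1.5%, 55.5% and 91.5% were recovered, with 0, 9 and 11 false calls. In the same test 60 lists of 20 unchanged genes had a mean percentile of 49.4, and a shifted list reached 100. Settings varied as planned were rescaling to a median ratio of 1, a mean of at least 10 or 100 or no minimum, 1.5-fold and 4-fold limits, and leaving out ribosomal protein, mitochondrial and unnamed genes. Settings added after the table was seen were an adjusted p of 0.01 or 0.1, a mean of at least 30, 100 or 1000 for the calls, centring each fold change on the median of genes of like mean with p taken again from the deposited standard errors, and the histone list without H19 and H13. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.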

Results

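RNA was sequenced from pancreas progenitor spheres, which are clusters of cells grown in Matrigel from dissociated dorsal pancreatic buds of mouse embryos (CD-1 strain, embryonic day 13.5). The cells were infected with lentivirus carrying a short hairpin RNA, either a scrambled control (shScramble, 1 sample) or a hairpin against Wdr5 (shWdr5, 1 sample), and selected with puromycin at 1 ug/mL. Retinoic acid at 0.33 uM was given daily at the start to make the spheres grow, a differentiation medium followed, and spheres were collected on day 7. Each sample was a pool of more than 4 sphere differentiations. The comparison asks what loss of WDR5, a shared core subunit of the trithorax group (TrxG) histone H3 lysine methyltransferase complexes, does to gene expression while progenitors differentiate. The authors' deposited table holds 18457 genes, with a mean normalised count between 1.56 and 559857 and a DESeq2 fold change for each. The number of libraries behind those fold changes and the depth of each library were not given in the sources used here. Nothing in the labels says that any libraries came from separate cultures beyond the pooling, so the p-values measure a spread that may be technical. Called acinar genes with a mean of at least 1000, given below, had larger standard errors than such islet genes, for a reason not tested.

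Wdr5 itself, at chromosome 2 from 27515147 to 27536535 (Entrez gene 140858, build GRCm38), was 3.87-fold lower in shWdr5 in the authors' deposited table. Its log2 fold change was -1.95 ± 0.44 (SE), with an adjusted p of 2.81e-04 (DESeq2 Wald test by the authors, Benjamini-Hochberg), at a mean normalised count of 2922. No other of the 20 TrxG and COMPASS subunits fixed for study passed an adjusted p of 0.05 there. The other 19 lay between -0.44 ± 0.48 for Kmt2c, a methyltransferase of the enhancer-associated complexes, and 0.69 ± 0.48 for Dpy30, another core subunit, in the authors' deposited table. Setd1a was listed at 0.63 ± 0.44. The median of the list was 0.12, at percentile 40.3 among random gene lists matched on mean expression, and Wdr5 was its only member past the threshold when p was adjusted over the list alone. Of 13 NSL complex members and other WDR5 partners, Mycn alone rose, to 1.87 ± 0.67 in the authors' deposited table (adjusted p = 0.0498, DESeq2, Benjamini-Hochberg), and it did not pass when adjusted over the list alone. Ogt (-0.93), Kansl2 (0.67) and Kat8 (0.56) did not pass, and that list's median was 0.34, at percentile 85.0. The direction of the deposited fold changes is not named in the table and was read from Wdr5.

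Across the transcriptome, genes lower in shWdr5 outnumbered genes higher. In the authors' deposited table, 1876 of the 17025 genes with an adjusted p passed 0.05 (DESeq2, Benjamini-Hochberg), of which 498 were higher and 1378 were lower. At an unadjusted p under 0.05, 1134 genes were higher and 2448 lower. By the rule of size set in advance, at least 2-fold with a mean of at least 30, there were 1125 genes higher and 2764 lower among 14716. Lower calls made up 73.5% of all calls and 62.4% (1038 lower, 626 higher) after each fold change was centred on genes of like mean, an adjustment added after the data were examined. The smallest change that passed was 2.30-fold. In simulated data with these standard errors and 200 of 14716 genes changed, 1.5% of 2-fold, 55.5% of 4-fold and 91.5% of 8-fold changes were recovered. The data held 1876 calls, and the Benjamini-Hochberg limit depends on how many genes change. The recovered shares therefore belong to the simulation and are not the recovery in the data.

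**Figure D1:**
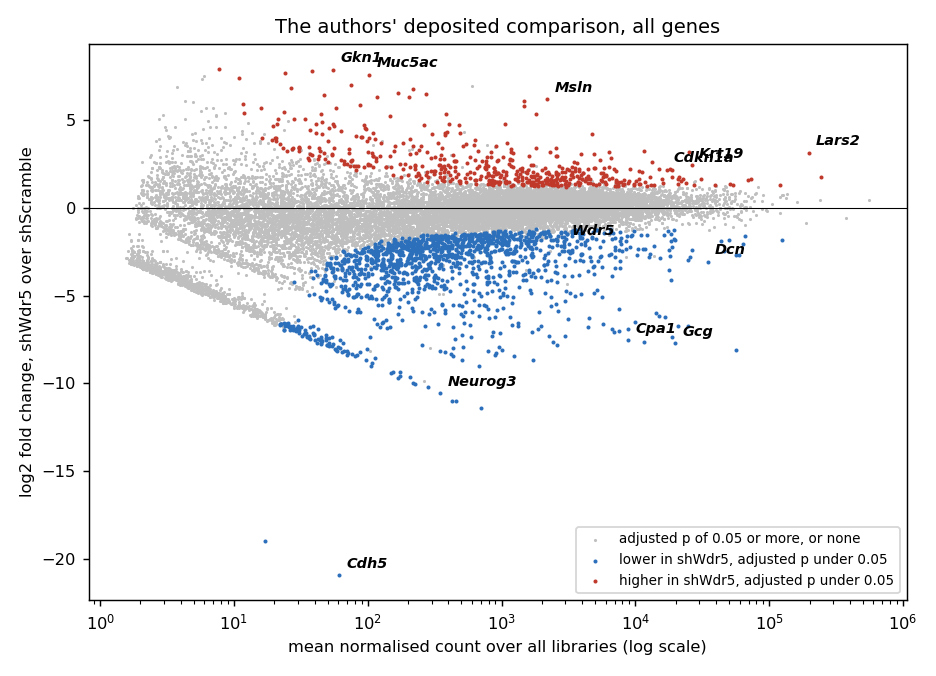
Each point is a gene of the authors' deposited table, with its mean normalised count over all libraries on the x axis (log scale) and its log2 fold change, shWdr5 over shScramble, on the y axis. Coloured points passed an adjusted p of 0.05, 498 higher (red) and 1378 lower (blue); Cdh5 lies at -20.89 with a standard error of 5.65, so its fold is not determined.

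The genes with the lowest fold changes included genes known from hormone-producing and enzyme-secreting cells. Among the 12 lowest in the authors' deposited table were Neurog3, the transcription factor that starts endocrine differentiation (-10.57 ± 2.14), and the trypsinogen gene Prss1 (-11.02 ± 3.02). Pdyn, the precursor of dynorphin peptides (-10.99 ± 2.20), the potassium channel gene Kcnh6 (-10.21 ± 2.12) and the lens crystallin gene Cryba2 (-9.35 ± 2.19) stood beside them. The receptor genes Oxtr (-9.66), Gabbr2 (-9.56) and Adra2a (-9.40), which encode the oxytocin, GABA-B and alpha-2A adrenergic receptors, were in the same group. Chodl (-11.40), Serpini2 (-9.69), Cldn11 (-9.36) and the vascular cadherin gene Cdh5 (-20.89 ± 5.65) completed the lowest 12 of the authors' deposited table. Standard errors exceeded 2 for all 12, as for 112 of the lower calls and 3 of the higher calls, so the sizes of these folds are poorly determined although their direction passed the test. The call for Cdh5, at a mean of 61.3, rests on a fold that is not determined, so its direction is less secure. At a like mean of 58.9, Plcxd3, picked out after its value was seen, was listed at -8.13 ± 2.23.

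The genes with the highest fold changes included several that encode products of mucosal surfaces. In the authors' deposited table, Gkn1, a secreted protein of the gastric surface mucosa, rose by 7.86 ± 1.15 and the gastric mucin gene Muc5ac by 7.57 ± 0.87 (adjusted p = 9.58e-10 and 1.30e-15, DESeq2, Benjamini-Hochberg). Muc5ac lies at chromosome 7 from 141788958 to 141819227. The hydrogen peroxide-producing oxidase gene Duox2 (6.75 ± 0.68) and its maturation factor Duoxa2 (6.29 ± 0.81) rose together in the authors' deposited table. Krt4, a keratin of stratified epithelia (6.42 ± 1.04), and Sprr2a3, a component of the cornified envelope (6.31 ± 0.68), also rose. Surface antigen genes Ly6a (5.76 ± 0.72), Ly6c1 (6.47 ± 0.60) and Msln, which encodes mesothelin (6.18 ± 0.52), were among the highest 12 of the authors' deposited table, as were Fam3b (7.76), Eps8l3 (6.97) and the glutathione transferase gene Gsta2 (6.52). Ly6a, Ly6c1, Sprr2a3 and Gsta2 belong to families of near-identical genes whose reads may be shared, so their single values are uncertain.

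Endocrine genes were lower, from transcription factors of progenitors to hormones. Of 22 endocrine progenitor genes, 15 fell and none rose, with a median log2 fold change of -3.22, below all 10000 random lists (percentile 0), and 17 were lower when adjusted over the list alone. Neurog3 lies at chromosome 10 from 62133090 to 62134763. It was followed in the authors' deposited table by the transcription factor genes St18 (-8.10 ± 0.96), Rfx6 (-7.30 ± 0.79) and Pax4 (-7.16 ± 2.37). Centring on genes of like mean left standard errors as deposited and moved Pax4 to -6.32, still far below 0, where its call ended (adjusted p = 0.0702, Benjamini-Hochberg on the authors' DESeq2 values). Of 26 islet hormone and secretory genes, 24 fell and none rose, with a median of -6.62 at percentile 0, and 25 were lower when adjusted over the list alone. In the authors' deposited table the glucagon gene Gcg was 208-fold lower (-7.70 ± 0.66, adjusted p = 3.35e-28, DESeq2, Benjamini-Hochberg) and the insulin gene Ins1 165-fold lower (-7.37 ± 0.65, adjusted p = 1.43e-26). The second insulin gene, Ins2, was listed there at -6.73 ± 0.65 and the somatostatin gene Sst at -8.08 ± 0.72. G6pc2, an islet glucose-6-phosphatase (-8.66 ± 0.99), and Pcsk1, a prohormone convertase (-7.84 ± 0.68), fell as far in the authors' deposited table. Markers of neurons and neural crest, part of which endocrine cells share, moved with these lists, with 8 of 10 lower and a median of -3.37.

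Digestive enzyme genes of acinar cells were lower as well. Of 23 acinar genes over the minimum, 18 fell and none rose, with a median of -6.33 at percentile 0, and 21 were lower when adjusted over the list alone. Markers of mesenchyme (9 of 22) and of neural crest and neurons (8 of 10) were lower in the same comparison. The carboxypeptidase gene Cpa1, which also marks early multipotent tip cells, was listed in the authors' deposited table at -7.54 ± 1.98 (adjusted p = 0.00270, DESeq2, Benjamini-Hochberg). The bile salt-stimulated lipase gene Cel (-8.43 ± 2.16), the elastase gene Cela2a (-8.40 ± 2.55) and the trypsinogen gene Try10 (-8.13 ± 2.56) fell in the authors' deposited table. Trypsinogen and amylase genes are near-identical copies, so values of single members such as Prss1 and Try10 are uncertain. Standard errors of acinar genes were large. For the 8 called acinar genes with a mean of at least 1000 they ran from 1.57 to 2.16, against 0.465 to 0.995 for the 19 called islet hormone and secretory genes of that mean. The median log2 fold changes of these acinar and islet genes were close, at -7.11 and -6.73. Mean and fold alone therefore do not account for the larger standard errors of these acinar genes. Without values per library, a technical spread and a biological one cannot be told apart. Large standard errors were not limited to acinar genes. Igf1 (-4.36 ± 1.76, mean 3072) and Serpina6 (-6.59 ± 2.05, mean 1326), picked out after their values were seen, also had them.

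Transcription factors of the early pancreas held 1 call in each direction, while their median was high among matched random lists. Of 19 pancreas progenitor factors over the minimum, Sox4 rose and Nkx6-1 fell, 17 did not pass, and the median was 0.47, at percentile 99.5. The same 1 higher and 1 lower passed when adjusted over the list alone. Nkx6-1, a homeodomain factor of the trunk and later of beta cells, was listed at -2.42 ± 0.60 in the authors' deposited table (adjusted p = 0.00127, DESeq2, Benjamini-Hochberg). Sox4 stood at 1.40 ± 0.43, a call that ended after centring, at 1.18 (adjusted p = 0.0594, Benjamini-Hochberg on the authors' DESeq2 values). Pdx1, the master regulator of pancreas identity, was listed at -0.63 ± 0.58 and the progenitor factor Sox9 at 0.99 ± 0.52 in the authors' deposited table, neither past the test. Gata4 (1.47 ± 0.56) and Foxa2 (1.33 ± 0.59) did not pass either, although Gata4 passed after centring, at 1.72 (adjusted p = 0.0250, Benjamini-Hochberg on the authors' DESeq2 values). Ptf1a, which is needed for the acinar fate, had a mean of 26.8, under the minimum, and a value of -6.78 ± 4.59 that did not pass. Ductal genes leaned the other way from endocrine and acinar genes, with 10 of 23 higher and 1 lower, a median of 0.53 at percentile 99.8, and 10 higher and 2 lower when adjusted over the list alone. Stomach, gut and liver genes leaned the same way as ductal genes, with 4 of 10 higher and 1 lower, and Lars2, Rpph1 and Rmrp rose too. In the authors' deposited table the duct keratin gene Krt19 was 5.40-fold higher (2.43 ± 0.42, adjusted p = 5.66e-07, DESeq2, Benjamini-Hochberg). Carbonic anhydrase gene Car2 (4.16 ± 0.59) and trefoil factor gene Tff2 (4.73 ± 0.49), the latter also a gastric mucosal product, rose, and the ceruloplasmin gene Cp (-2.61 ± 0.73) fell in the authors' deposited table.

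**Figure D2:**
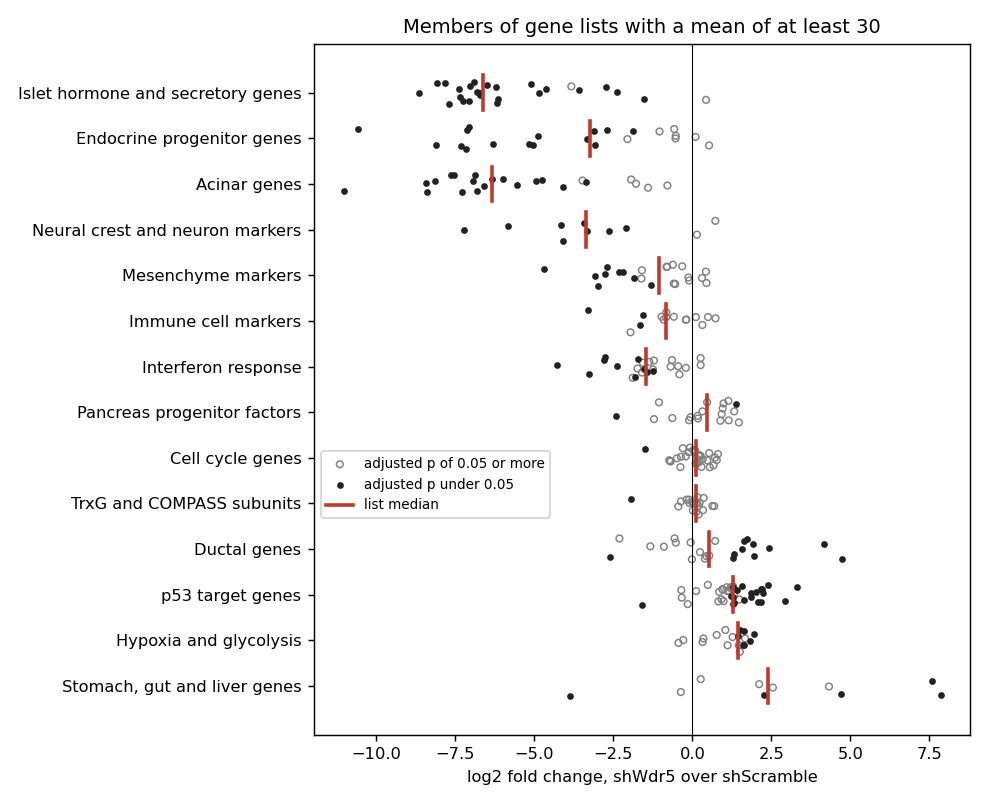
Each circle is a member of a gene list, for part of the lists, with a mean normalised count of at least 30, placed by its log2 fold change, shWdr5 over shScramble, on the x axis; vertical jitter only separates the points. Filled circles passed an adjusted p of 0.05 and red bars mark list medians, which among the lists drawn run from -6.62 for islet hormone and secretory genes to 2.41 for stomach, gut and liver genes; erythroid markers (median 3.39) are among those not drawn.

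Targets of the tumour suppressor p53 were higher. Of 39 p53 target genes, 19 rose and 1 fell, with a median of 1.28 above all 10000 random lists (percentile 100), and 28 were higher and 1 lower when adjusted over the list alone. Lars2, Rpph1 and Rmrp, possible signs of RNA handling given with the stomach genes, also rose, and a link was not tested. The cell cycle inhibitor gene Cdkn1a was 4.49-fold higher in the authors' deposited table (2.17 ± 0.43, adjusted p = 2.52e-05, DESeq2, Benjamini-Hochberg), at chromosome 17 from 29090979 to 29100722. Mdm2, the ubiquitin ligase that restrains p53, was listed there at 2.08 ± 0.43. The stress cytokine gene Gdf15 (3.31 ± 0.47), the desmosomal gene Perp (2.92 ± 0.44), Dglucy (2.41 ± 0.51) and the RNA-binding protein gene Zmat3 (2.25 ± 0.42) rose in the authors' deposited table. The exception was Sesn1, at -1.60 ± 0.52, picked out after its value was seen. Trp53 itself did not pass, at 0.78 ± 0.44. Of 32 cell cycle genes, 31 did not pass, none rose, and Ccne2, an S-phase cyclin, fell to -1.50 ± 0.48 in the authors' deposited table (none passed when adjusted over the list alone). The proliferation marker Mki67 stood at -0.38 ± 0.54, Ccnb2 at -0.73, Aurka at 0.77 and Rrm2 at 0.81. The cell cycle median was 0.11, at percentile 35.0.

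**Figure D3:**
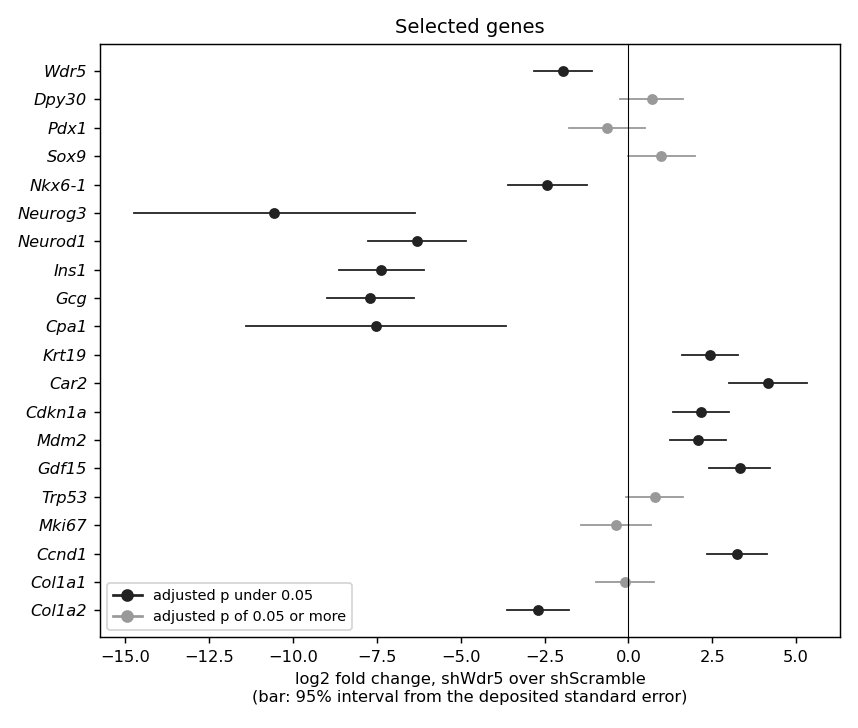
Log2 fold changes of selected genes, shWdr5 over shScramble, from the authors' deposited table are on the x axis, and bars are 95% intervals from the deposited standard errors. Black points passed an adjusted p of 0.05 and grey points did not, among them Pdx1 (-0.63), Sox9 (0.99) and Mki67 (-0.38).

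Genes of hypoxia and glycolysis rose in part, 7 of 18 with none lower, a median of 1.46 at percentile 100, and 11 higher when adjusted over the list alone. In the authors' deposited table these included Bnip3, a mitophagy receptor (1.96 ± 0.58), Ndrg1 (1.82 ± 0.45) and the glycolytic enzyme gene Aldoa (1.64 ± 0.45), while Adm, the adrenomedullin gene, did not pass at 1.67 ± 0.64. Lars2, Rpph1 and Rmrp, the possible signs of RNA handling, rose beside this list too. After centring Adm passed, at 1.92 (adjusted p = 0.0330, Benjamini-Hochberg on the authors' DESeq2 values). Of 23 genes of the unfolded protein and amino acid stress response, 3 rose (also 3 adjusted over the list alone), none fell, and the median was 0.38, at percentile 95.3. The 3 were the stress regulator genes Nupr1 (2.14 ± 0.51) and Ddit4 (1.82 ± 0.49) and the cystine transporter gene Slc7a11 (2.02 ± 0.48) in the authors' deposited table, whereas Chac1 stood at 1.08 ± 0.54. Interferon response genes were lower, with 10 of 24 falling, none rising, a median of -1.48 at percentile 0, and 17 lower when adjusted over the list alone. Antiviral genes Ifi44 (-4.28 ± 1.09), Mx2 (-3.27 ± 0.81), Oas1a (-2.80 ± 0.81) and Rtp4 (-2.77 ± 0.75) had the lowest values of that list in the authors' deposited table. Immune markers (median -0.82, 3 of 15 lower) and mesenchyme markers (median -1.05, 9 of 22 lower) moved in the same direction as these genes. The call for Oas1a ended after centring, at -2.02 (adjusted p = 0.0988, Benjamini-Hochberg on the authors' DESeq2 values).

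Signalling lists were mixed. Of 17 Notch pathway genes, 2 rose and 2 fell, with a median of -0.18 at percentile 60.2 that turned to 0.24 after centring, and 3 rose and 3 fell when adjusted over the list alone. The ligand gene Jag1 rose (2.23 ± 0.46) with the feedback gene Nrarp (2.65 ± 0.83), and the ligand gene Dll4 (-4.45 ± 1.08) fell with Mfng (-4.81 ± 1.28) in the authors' deposited table. Of 11 Wnt pathway targets, 3 rose and 1 fell, while the median was -0.68 at percentile 9.48, so the called members and the median differ in sign. Adjusted over the list alone, 3 were higher and 3 lower. The cyclin gene Ccnd1 (3.24 ± 0.46), Sox17 (2.47 ± 0.73) and the receptor-clearing ligase gene Rnf43 (2.10 ± 0.53) rose, and Notum stood at -3.44 ± 1.43 without passing, in the authors' deposited table. The gene that fell was the feedback gene Axin2 (-1.67 ± 0.53), picked out after its value was seen. Of 12 retinoic acid genes, 2 fell, with a median of 0.14 at percentile 79.0, and 1 was higher and 2 lower when adjusted over the list alone. The retinaldehyde dehydrogenase genes Aldh1a2 (-3.93 ± 0.80) and Aldh1a3 (-3.73 ± 0.81) fell, and Aldh1a1 (1.55 ± 0.57) and Crabp1 (-2.07 ± 1.16) did not pass, in the authors' deposited table. After centring Aldh1a1 passed, at 1.69 (adjusted p = 0.0334, Benjamini-Hochberg on the authors' DESeq2 values).

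Housekeeping and chromatin lists held few calls. None of 19 cholesterol synthesis genes passed, over all genes or over the list alone, and their median was -0.41 at percentile 0.050, with values of -1.15 for Lss, -0.86 for Idi1 and -0.64 for Mvd in the authors' deposited table. After centring Lss passed, at -1.34 (adjusted p = 0.0403, Benjamini-Hochberg on the authors' DESeq2 values). Of 83 genes taken by the ribosomal protein name pattern, Rps27l rose (1.43 ± 0.49) and Rpl7l1 fell (-1.73 ± 0.44) in the authors' deposited table. The pattern also takes like-named genes with an added l, as both are, so neither call stands for the ribosomal proteins as a group. The call for Rps27l ended after centring, at 1.23 (adjusted p = 0.0955, Benjamini-Hochberg on the authors' DESeq2 values). Rpl23a (1.18) did not pass, the median was -0.04 at percentile 0.030, and only the lower gene passed over the list alone. Of 24 genes taken by the histone name pattern, Hist2h2be fell (-1.68 ± 0.57, a call that ended after centring, where it was -1.43), none passed over the list alone, and the median was 0.45 at percentile 99.97. That median was -0.00859 among members with a mean of at least 100 and 1.13 after centring. The cell cycle median stood at percentile 35.0, while Lars2, Rpph1 and Rmrp, possible signs of RNA handling, rose. Whether RNA handling moved the histone list was not tested. Hist1h1a (2.21), Hist1h1b (2.14) and Hist1h4h (1.92) did not pass, although Hist1h1b passed after centring, at 2.93 (adjusted p = 0.0161, Benjamini-Hochberg on the authors' DESeq2 values). The histone pattern also took H19 and H13, which are not histone genes, and without them the median of 22 was 0.58. None of 19 Hox genes passed by either adjustment, with a median of -0.38 at percentile 35.5 and the lowest values at Hoxd3 (-4.15), Hoxd8 (-2.34), Hoxa6 (-1.98) and Hoxb8 (-1.04) in the authors' deposited table. For mitochondrially encoded genes 0 rows were found.

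Some markers of cells other than the epithelium fell. Of 22 mesenchyme markers, 9 fell and none rose, with a median of -1.05 at percentile 0, and 10 were lower when adjusted over the list alone. The matrix proteoglycan genes Lum (-4.69 ± 0.53) and Dcn (-3.07 ± 0.43), the growth factor receptor gene Pdgfra (-2.99 ± 0.43) and the homeobox gene Prrx1 (-2.75 ± 0.61) fell in the authors' deposited table. Of 10 neural crest and neuron markers, 8 fell (also 8 over the list alone), with a median of -3.37 at percentile 0. Sox10 (-7.23 ± 2.46), Elavl4 (-5.82 ± 0.84) and Tubb3 (-4.16 ± 0.61) led that list in the authors' deposited table, and the call for Sox10 ended after centring, at -6.44 (adjusted p = 0.0779, Benjamini-Hochberg on the authors' DESeq2 values). Of 15 immune markers, 3 fell (4 over the list alone), with a median of -0.82 at percentile 0.47. These were the macrophage genes Mrc1 (-3.31 ± 0.68), Lyz2 (-1.55 ± 0.51) and Adgre1 (-1.66 ± 0.59) in the authors' deposited table, Adgre1 no longer after centring, at -1.57 (adjusted p = 0.0729, Benjamini-Hochberg on the authors' DESeq2 values), while Itgam (-1.96) did not pass. Of 8 endothelium markers, Cdh5 and Pecam1 (-3.71 ± 1.30) fell, also over the list alone, with a median of -1.34 at percentile 6.87, and Plvap (-1.64) and Flt1 (-1.51) did not pass. The call for Pecam1 ended after centring, at -2.85 (adjusted p = 0.179, Benjamini-Hochberg on the authors' DESeq2 values). The call for Cdh5 held, but it rests on a fold that is not determined. No erythroid marker of 6 passed by either adjustment, with a median of 3.39 at percentile 100 and standard errors of 2.30 to 4.15 for Hba-a1 (3.55), Hbb-y (3.47), Hba-x (3.32) and Hbb-bs (3.79).

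Genes of neighbouring endodermal organs gave mixed results. Of 10 stomach, gut and liver genes over the minimum, 4 rose and 1 fell, with a median of 2.41 at percentile 100, and 6 were higher and 1 lower when adjusted over the list alone. With Gkn1 and Muc5ac, the gastric annexin gene Anxa10 rose (4.72 ± 0.64) in the authors' deposited table, and the trefoil factor gene Tff1 did not pass at 4.32 ± 2.14. The remaining calls, picked out after their values were seen, were the microvillus gene Vil1, which rose (2.26 ± 0.46), and the albumin gene Alb, which fell (-3.87 ± 1.15), in the authors' deposited table. Possible signs of RNA handling moved in the same direction as these genes. Lars2, a mouse gene known to collect reads of ribosomal RNA, had a mean of 197663 and rose by 3.13 ± 0.52 in the authors' deposited table, and the structured RNA genes Rpph1 (3.69 ± 0.87) and Rmrp (3.25 ± 0.90) also rose. These 3 were picked out after their values were seen. The structured RNA list had 11 genes with a deposited value, and only these 3 were over the minimum mean. The others were not assessed, so the 3 do not stand for structured RNA as a class.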

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

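Tests at other adjusted p limits, other minimum means for the calls, centring on genes of like mean and the shortened histone list were chosen after the results were seen, and the others were planned. Before rescaling, the median log2 fold change of genes over the minimum was -0.00858, so rescaling could change little. Wdr5 stayed lower and past the threshold after rescaling (-1.94) and centring (-2.12). Its sign had set the direction of all fold changes, so this is no check of that direction. Without a minimum mean, 1688 genes were at least 2-fold higher and 4577 lower, because more genes were counted. A 1.5-fold limit gave 2677 higher and 4034 lower, and a 4-fold limit gave 293 higher and 1305 lower, by construction. At an adjusted p of 0.01, 294 genes were higher and 872 lower, and among genes with a mean of at least 1000 there were 245 higher and 358 lower calls, again by construction (DESeq2 by the authors, Benjamini-Hochberg). Of the calls, 417 higher and 973 lower genes were also called after centring. Of 145 named genes with an adjusted p, 8 lost their call after centring (Adgre1, Hist2h2be, Oas1a, Pax4, Pecam1, Rps27l, Sox10 and Sox4), 5 gained one (Adm, Aldh1a1, Gata4, Hist1h1b and Lss) and none changed sign while called, and rescaling ended only the call for Adgre1. Of 25 list medians, the histone median turned to -0.00859 at a mean of at least 100, and the cause was not tested. The other 24 moved by less than their members' median standard error under each of these settings, although the small medians of the TrxG, cell cycle and Notch lists changed sign after centring (-0.09, -0.05 and 0.24). Other pseudocounts, total-count and TMM scaling, leaving out replicates and other splits of the samples were not run, since they need values per library. Depth per library is unknown, and no change under 2.30-fold passed the deposited test.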

Other observations

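Chosen after the results were seen were the tests on genes with a mean of 100 to 300 and on the spread of mesenchyme markers. The YAP, NRF2, receptor and stomach gland lists were written after the table was seen but before their own values were. Targets of NRF2, the transcription factor of the oxidative stress response, were higher in shWdr5. Of 16, 10 rose and none fell in the authors' deposited table, 13 were higher when adjusted over the list alone, and the median of 1.498 stood at percentile 100 of matched random lists. Gsta4, a glutathione transferase (2.82 ± 0.56), Txnrd1, a thioredoxin reductase (2.21 ± 0.43), Pgd, an enzyme of the pentose phosphate pathway (2.08 ± 0.44), and Gsr, glutathione reductase (1.82 ± 0.44), led the list in the authors' deposited table. The list was written because the related gene Gsta2 was among the highest 12, and its result is consistent with a wider NRF2 response as a hypothesis. Lists of p53 targets and of hypoxia and glycolysis also reached percentile 100, so the list does not stand alone among stress genes. Stomach, gut and liver genes and erythroid markers, of which 0 of 6 passed, reached percentile 100 too. Lars2, Rpph1 and Rmrp rose in the same comparison, and a link was not tested.

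The following genes were picked out after their values were seen and stand for no group. In the authors' deposited table the growth factor gene Areg rose by 5.35 ± 0.59, the gastric claudin gene Cldn18 by 4.18 ± 0.68, the prostate stem cell antigen gene Psca by 4.77 ± 0.94 and the clusterin gene Clu by 1.72 ± 0.50. Gkn2, a partner of Gkn1, rose by 7.64 ± 1.63 at a mean of 24.2, under the minimum. The gastrin gene Gast, made by endocrine cells, fell, at -6.86 ± 1.61 in the authors' deposited table, and the forestomach and neural factor gene Sox21 rose (3.00 ± 0.95).

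While the gastric surface genes Gkn1 and Muc5ac rose and Tff1 did not pass, genes of stomach glands and forestomach had a median of -0.00698 over 13 (95% bootstrap interval -1.95 to 1.11). For stomach tissue among the shWdr5 cells 1 or more was predicted, a bound that took no account of lower folds at low means. The 6 members over the minimum had a median of 0.02 at percentile 86.1 of matched random lists, whose typical median was -0.62. Of these 6, 1 rose and 1 fell, and 1 was higher and 2 lower when adjusted over the list alone. The members went both ways and 7 of the 13 were under the minimum mean, so stray stomach tissue stays open. Targets of YAP and TAZ, which respond to cell shape and stiffness, had a median of 0.51 at percentile 99.3, so higher expression of these targets may be part of the pattern, as a hypothesis. The percentile was the test, pancreas progenitor factors stood as high (99.5), activity was not measured, and 2 of 21 rose, Ajuba (1.61) and Ptpn14 (1.23), and 4 were higher when adjusted over the list alone. A change of fate in cells that lost WDR5 was not tested, and the rise of Lars2, Rpph1 and Rmrp leaves a difference in RNA handling open.

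Fold changes went with mean expression, with a median log2 fold change of -1.01 for means under 10, -0.88 from 30 to 100, -0.14 from 300 to 1000 and 0.22 from 10000 up. At means of 100 to 300, 1779 genes still had a median of -0.70 (95% bootstrap interval over genes -0.77 to -0.64). A detection limit of a few reads in shWdr5 alone would not give that median. This range is part of the pattern itself, its value was known when it was chosen, and the mean is over all libraries. It therefore does not decide whether such a limit acts on genes of lower mean. More background reads in the control and loss of endocrine and neural cells cannot be told apart. The 39 receptor genes of other organs had a median of -0.35 with an interval from -1.80 to 0.09. They were chosen as genes that endocrine and neural cells should not bring, an assumption that was not tested. Of the 39, 5 were over the minimum mean, with a median at percentile 69.0 of matched random lists, whose typical median was -0.72. Differences in depth or kit between libraries were not tested, as no value per library was at hand.

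Of 22 mesenchyme markers, 9 fell and 13 did not pass. Cochran's Q over all 22 was 164.6, where equal decreases would give about 21 (its degrees of freedom, with markers taken as independent). The markers thus differed by more than the deposited standard errors, which are too small if the libraries share cultures. Their spread was known when the test was chosen, and other cells may carry some of the markers. The test therefore gives no verdict on a lower share of mesenchymal cells. The paired chains of type I collagen, picked out after their values were seen, show the spread, with Col1a2 at -2.68 ± 0.47 and Col1a1 at -0.10 ± 0.44 in the authors' deposited table. A lower share of some mesenchymal cells, with other cells carrying the markers that held, and a change of expression within those cells both stay open.

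Standard errors differed between genes of like mean and fold change. Among 2575 genes with a mean of at least 1000 and a log2 fold change within 0.25 of 0, the 95th percentile of the standard error was a median of 1.29 times the 5th over 10 bins of mean (range 1.25 to 1.32). The 8 called acinar genes with a mean of at least 1000 had standard errors from 1.57 to 2.16. Those of the 19 such islet genes ran from 0.465 to 0.995, at close median folds. With 1 library in each group, a standard error would follow from mean and fold. These values therefore argue against a single library in each group. The number of libraries behind these standard errors was not given in the sources used here.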
